A study of Mus musculus with 2 samples.

How the data were processed

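The data are droplet-based single-cell RNA counts from flow-sorted adipocyte precursor cells of subcutaneous adipose tissue from cross-fostered mouse pups aged 12 days, 1 sample for each of 2 milk fat conditions. The deposited matrix holds whole-number UMI counts per gene and cell barcode, which the authors had not normalized. Per the submitters' processing notes, Cell Ranger (version not given) and Seurat 3.0.1 were used with the mm10 build, with no role stated for either tool. Whether barcodes were filtered further, or reads subsampled, when the libraries were joined is not given in the sources used here. Per the labels, the library chemistry was 10x Genomics 3′ version 2, and cells are described both as fresh and as cryopreserved and thawed. The labels state 3000 sorted cells per condition, beside 3321 barcodes with suffix 1 and 3584 with suffix 2. No label assigns a suffix to a condition, so the libraries were compared with no diet attached and no diet comparison was made. Of the 16-base barcode sequences, 17 occurred in both libraries.

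The matrix had 27998 genes, 6905 barcodes and 19963973 nonzero entries. Barcodes were kept with at least 500 detected genes and at most 10% of counts from mitochondrially encoded genes. In library 1, 4 barcodes had fewer genes and 12 had a higher mitochondrial share, and in library 2 these numbers were 0 and 6. Scrublet as in scanpy was run per library with its automatic threshold. It called 8 of 6905 barcodes (0.116%), 5 in library 1 and 3 in library 2, a share so low that doublet calling is taken to have not worked, and doublets remain among the kept cells. After these steps 3302 and 3575 cells were kept, with 5th to 95th percentiles of 4773 to 19015 UMIs in library 1 and 5506 to 17881 in library 2.

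Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 gave 10 clusters. Genes of the fixed lists, mitochondrially encoded, ribosomal protein and cycling genes, 425 in all, were left out of the variable genes. The 18 marker lists, 15 gene lists, filters, comparisons, rule for named genes and most alternatives were set before the data were examined. A marker counted as raised with at least 20 CPM and at least 2-fold over all other cells, and a cluster took a name with at least 3 raised markers that made up at least 33.3% of the list. These thresholds for naming were set after the data were seen. Leading genes of a cluster needed 50 CPM, and their folds used a prior of 5 CPM. Of the listed genes, Trbc2 and Cebpd were not found by symbol and were not used here. Some results are not reported here. The oxidative phosphorylation list was taken by symbol prefix and includes 11 assembly factors.

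Counts were summed per class and library. Classes were compared as CPM of the total count, and libraries as CPM scaled by TMM (edgeR 4.0.16, used for scaling only) within Dpp4-type cells. Sums have exact Poisson intervals, ratios conditional exact intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. List members needed 10 CPM in at least 1 of the sums compared. The interval of a list median came from 500 Poisson resamples, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. With 1 library per condition no p-value was computed. Named genes were list members with high levels or large folds and, per comparison, up to 10 genes in each direction with at least 50 CPM and 2-fold or more apart, or 1.5-fold where fewer than 5 passed. Ribosomal protein genes, mitochondrially encoded genes and Gm and Rik models were left out of that rule. Between classes it was applied to list genes that name no class in that comparison. Further list members given as examples were chosen after their values were seen, C3, Ifit1, Fasn and Scd1 among them. Coordinates are those of the GENCODE annotation for GRCm38, and 57 of 57 genes looked up were found by identifier.

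A cell counted as cycling with 2 or more UMIs of Mki67 or Top2a. For thinning, each cell was reduced to 7464 UMIs, the 10th percentile, which left out 375 and 313 shallower cells. For a test of depth, Dpp4-type cells of each library were split at their median depth. Xist-positive cells had at least 4 Xist UMIs and none of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), and Y-positive cells at most 1 Xist UMI and at least 1 Y-linked UMI. These classes of cells were set after the data were seen, and the labels used here give no sex of the pups.

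Alternatives covered the cell filters, doublets, clustering, scaling (total count, TMM and DESeq2 1.42.0 size factors), level minimum, thinning and the cells compared. The comparison of libraries was tested on simulated counts with counting error only, in which 2229 genes were at or above the level minimum. For 100 genes given a 1.5-fold change the median log2 fold recovered was 0.58, and for 100 genes given a 3-fold change it was 1.59. Of 2030 unchanged genes, 0 passed 1.5-fold, and 93.8% had an interval that held 0. A list whose computed log2 folds were raised by 0.3 had a percentile of 100, a value that this raise largely sets. An unchanged list had one of 37.4. This test does not cover spread beyond counting error. Log2 folds between the real libraries had a standard deviation of 0.25. That value includes the 4 haemoglobin genes described below, at -5.58 to -5.09, which widen it. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.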

Results

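Single-cell transcriptomes were collected from adipocyte precursor cells, the fibroblast-like cells that give rise to fat cells. The cells were flow-sorted from subcutaneous adipose tissue of mouse pups aged 12 days. The pups had been fostered by dams whose milk fat had either a high or a low ratio of n-6 to n-3 polyunsaturated fatty acids. Per the labels, each of these 2 conditions contributed 1 sample of 3000 sorted cells, captured with droplet chemistry that reads the 3′ ends of transcripts and tags each molecule with a unique molecular identifier (UMI). By its title, the study asks how the fatty acid ratio received by neonates bears on lipid oxidation in these precursors. The count matrix joins both libraries and parts them by a barcode suffix, and no label ties a suffix to a diet. Libraries 1 and 2 are therefore given with their own values and no diet attached, and most comparisons are between cell classes. With 1 library per condition there is no replicate, so every interval covers counting error only.

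The matrix held 27998 genes and 6905 barcodes, of which 6877 were kept as cells. Library 1 had 3321 barcodes and 42092816 UMIs, and its 3302 kept cells had a median of 12962 UMIs and 3008.5 genes. Library 2 had 3584 barcodes and 43491307 UMIs, and its 3575 kept cells had a median of 12111 UMIs and 2879 genes. Mitochondrially encoded transcripts took a median of 1.73% of UMIs in library 1 and 1.77% in library 2. Both barcode counts were above the 3000 cells per condition that the labels state were sorted.

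The first question was which cells the sort had collected. Precursor clusters held 98.4% of the kept cells (6764 of 6877, 95% exact binomial interval 98.0 to 98.6). A cluster counted as precursor unless its name was that of a cell type outside the lineage. Unnamed clusters 2, 3 and 6, described below, are therefore included although they met the rule for no name. The largest class, called Dpp4-type progenitor-like after the surface peptidase that marks early interstitial progenitors, held 2820 cells, or 41.0% (39.8 to 42.2). Committed preadipocyte-like cells, with Lpl and the basement membrane collagen genes Col4a1 and Col4a2 among their raised markers, held 1765 cells, or 25.7% (24.6 to 26.7). F3-type stromal-like cells, named after the gene for coagulation factor III, held 408 cells, or 5.93% (5.39 to 6.52), and cycling-like cells held 222, or 3.23% (2.82 to 3.67). The shares of the precursor classes depended on the settings of the clustering. At a finer Leiden resolution of 1, the Dpp4-type share was 16.1% and the committed share 18.6%.

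The Dpp4-type class was led by Krtdap, Bmp7, Igfbp5, Akr1c18 and Cthrc1, and 10 of its 12 markers were raised, among them Pi16, Wnt2 and Anxa3. The committed class was led by Gm2564, Col15a1, Prlr, Steap4 and Rgs16, with 8 of 12 markers raised. Mgp, Ifitm1, Vtn, Vit and C2 led the F3-type class, with 6 of 7 markers raised. Hist1h2ap, Ube2c, Top2a, 2810417H13Rik and Birc5 led the cycling-like class, in which all 14 markers were raised. Clusters 2 (1015 cells, 14.8%), 3 (452 cells, 6.57%) and 6 (82 cells, 1.19%) did not meet the naming rule and stayed unnamed. Smpd3, Daglb, Gas7 and Adm were among the genes that led cluster 2. The leading genes were Cilp, C1qtnf3, Eln, Car3 and Mfap4 in cluster 3, and Hist1h1c, Hist1h2bc, Ccnb2, Cenpa and Lockd in cluster 6. Pdgfra, the receptor commonly used to gate adipocyte precursors, lay between 72.1 and 165 counts per 1000000 counts (CPM) over clusters 0 to 6. It was at 83.0 CPM in macrophage or monocyte-like cluster 8, 34.6 CPM in cluster 9 and 29.2 CPM in cluster 7, so its level alone does not part the precursor clusters from the rest.

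Cells of clusters named as types outside the precursor lineage were few. Endothelial-like cells (49, 0.713%) were led by Cldn5, Cdh5, Gpihbp1, Rbp7 and Rgs5, and they also carried raised markers of mural cells (6 of 8), adipocytes (5 of 8), committed preadipocytes (7 of 12) and erythroid cells (5 of 5). Over both libraries their median of 19074 UMIs was above that of every other cluster, so this cluster can hold doublets, which the doublet caller did not resolve. In library 2 alone their median was 14029.5 UMIs, below the 15865 of cycling-like cells. Unnamed cluster 2 had a higher median doublet score (0.0918 beside 0.0832), so doublets may not be limited to endothelial-like cells. Macrophage or monocyte-like cells (46, 0.669%) were led by Cd74, Lyz2, Pf4, Retnla and C1qc and also had 4 of the 6 measured lymphocyte markers, 5 of 8 endothelial markers and 6 of 14 cycling markers raised. Erythroid-like cells (18, 0.262%) were led by Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Alas2. No cluster had 3 or more raised markers of lymphatic endothelium, mast cells or granulocytes, Schwann cells, mesothelium, or tendon and cartilage. No marker of the muscle lineage or of epithelium was raised in any cluster.

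Set side by side under this clustering, the libraries had shares of Dpp4-type, committed and F3-type cells with overlapping intervals. Dpp4-type cells made up 40.9% of library 1 (39.3 to 42.6) and 41.1% of library 2 (39.4 to 42.7). For committed cells these shares were 25.8% (24.3 to 27.3) and 25.6% (24.1 to 27.0), and for F3-type cells 5.78% (5.01 to 6.64) and 6.07% (5.31 to 6.90). Cycling-like cells made up 2.48% (1.98 to 3.07) and 3.92% (3.30 to 4.60), intervals that did not overlap. Other clusterings set the libraries apart in other ways. At Leiden resolution 1, Dpp4-type cells made up 19.3% of library 1 (18.0 to 20.7) and 13.2% of library 2 (12.1 to 14.3), while with 3000 variable genes they made up 45.5% (43.7 to 47.2) and 49.3% (47.7 to 51.0). With listed genes among the variable genes these shares were 35.8% (34.2 to 37.5) and 39.6% (38.0 to 41.2). With predicted doublets kept, committed cells made up 16.8% (15.6 to 18.1) and 20.3% (19.0 to 21.7). The cycling-like share was higher in library 2 under each clustering tried, but of the alternatives only Leiden resolution 1 kept its intervals apart, and with 3000 variable genes the shares were 4.72% (4.03 to 5.50) and 5.87% (5.13 to 6.70). The erythroid-like cluster held 0.545% of library 1 (0.323 to 0.860) and 0 of 3575 cells of library 2, an upper bound of 0.103%. That bound is on membership of this cluster, not on haemoglobin transcripts. In library 2, 10 of 26 endothelial-like cells held an Hbb-bs UMI. The shares of clusters 2 and 3 are not compared, because genes that lead them differed between the libraries.

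**Figure D1:**
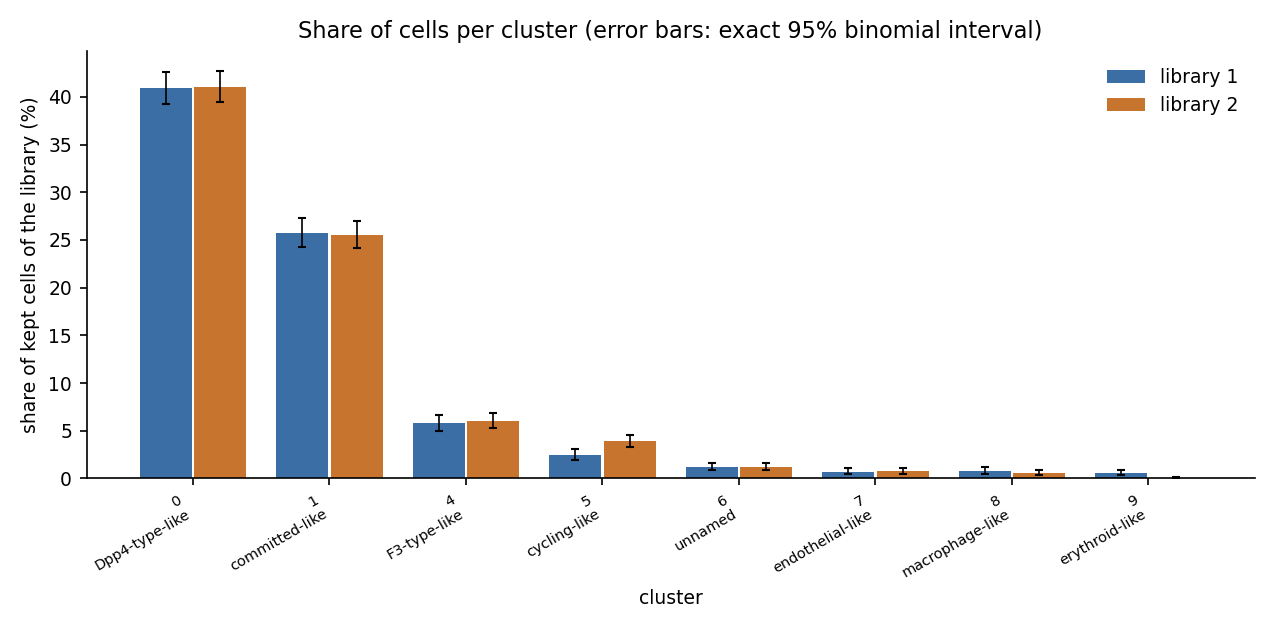
Share of kept cells (%) in each cluster, with library 1 and library 2 as separate bars and exact 95% binomial intervals as error bars; clusters 2 and 3 are left out. Dpp4-type cells stand at 40.9% and 41.1%, and erythroid-like cells at 0.545% and 0%.

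The next comparison asked how committed preadipocyte-like cells differ from Dpp4-type progenitor-like cells in gene lists fixed before the data were examined and left out of the clustering. Committed cells carried more transcripts of chemokines, and fewer of both cyclooxygenases and of the prostaglandin-inactivating enzyme Hpgd. The inflammatory and chemokine list was higher by a median log2 fold of 1.06 (95% interval 1.04 to 1.11), with 15 of its 16 measured members higher, and by 1.09 in library 1 and 1.15 in library 2. The oxylipin and prostanoid list was lower, at -0.38 (-0.64 to -0.27), with 7 of 11 members lower. Fatty acid oxidation had a median of -0.13 (-0.18 to -0.067), with 6 members higher and 17 lower. All 6892 genes compared had a median of -0.11 under the same scaling. The percentile of this list among matched random lists was 45.5, so it was not set apart from other genes.

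Within the inflammatory list, Cxcl12, a chemokine that attracts haematopoietic cells, stood at 207 CPM (203 to 212) in Dpp4-type and 586 CPM (575 to 597) in committed cells. Il1r1, the receptor for interleukin 1, was higher by 2.13 and Vcam1, an adhesion molecule for leukocytes, by 1.44. Ccl11, which attracts eosinophils, was higher by 1.28, the neutrophil chemokine Cxcl1 by 1.24 and the cytokine Il6 by 1.13. Il33 was the member with a lower level, at -0.65. The list stood above all 10000 random lists matched on expression (percentile 100). Icam1 belongs to it and also names the committed class, and the median without class markers was 0.99. The interferon response list, of 5 measured members, had a median of 1.08 (percentile 99.96), with Isg15, a ubiquitin-like modifier, at 2.53. It was 0.60 (0.37 to 0.97) in library 1 and 1.45 (1.27 to 1.56) in library 2, and 0.34 with members of at least 50 CPM.

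Members of the oxylipin and prostanoid list differed in both directions. Ptgs2, the inducible cyclooxygenase, stood at 140 CPM (136 to 144) in Dpp4-type and 37.4 CPM (34.8 to 40.2) in committed cells, a log2 fold of -1.90. Ptgs1, its constitutive counterpart, was lower by a log2 fold of -2.68, and Hpgd, which inactivates prostaglandins, by -1.89. Pla2g4a, the phospholipase that frees arachidonic acid, was at -1.19 and Ptgis, prostacyclin synthase, at -0.79. In contrast, the prostaglandin E synthases Ptges and Ptges3 were higher by 0.22 and 0.13, the prostaglandin E receptor Ptger3 by 3.71 and the prostacyclin receptor Ptgir by 3.42, at 15.7 and 11.7 CPM in committed cells. The list median had a percentile of 3.21, was -0.76 in library 1 and -0.53 in library 2, and reached -1.34 over members with at least 50 CPM.

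Lists of energy metabolism differed by amounts that depended on scaling and clustering. Among genes of fatty acid oxidation, Ucp2, a mitochondrial carrier, was higher in committed cells (7.76 and 18.8 CPM, log2 fold 1.28), as was Hadh at 0.28. Etfa, which passes electrons from acyl-CoA dehydrogenases to the respiratory chain, was lower at -0.56, Cpt1a, which controls fatty acid entry into mitochondria, at -0.52 and Cpt2 at -0.66. The percentile of this list was 45.5, its median was -0.11 in each library, and it was -0.043 with TMM scaling and -0.29 at Leiden resolution 1. Nuclear-encoded oxidative phosphorylation had a median of -0.015 (-0.027 to 0.0062, percentile 69.0) with 41 members higher and 45 lower, and its sign was not settled, at -0.083 with Leiden resolution 1, 0.079 with TMM scaling, 0.015 with listed genes among the variable genes and 0.0093 with 3000 variable genes. Mitochondrially encoded genes had a median of 0.049 (percentile 63.3), at 0.013 in library 1 and 0.061 in library 2, and 0.14 with TMM scaling. The tricarboxylic acid cycle stood at -0.080 (percentile 59.0), a sign that flipped to 0.012 with TMM scaling, and at -0.25 at Leiden resolution 1. Glycolysis was lower at -0.25 (percentile 8.17) with 10 of 13 members lower, at -0.16 with TMM scaling and -0.47 at Leiden resolution 1. Hk2, which traps glucose in the cell, went the other way at 1.10, and the lactate and pyruvate carrier Slc16a3 was at -1.89. Total scaling put the median of all 6892 genes at -0.11 and TMM put it at -0.017. The shift between these scalings was 0.092 over both libraries and 0.10 in library 2.

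Genes of lipid synthesis and desaturation had a median of -0.15 (-0.25 to -0.013, percentile 43.3), which flipped to 0.057 over members with at least 50 CPM. Scd2, a stearoyl-CoA desaturase, was lower at -1.04 and Scd1 at -0.94, whereas Elovl6, which lengthens fatty acids, was at 0.58 and Fasn, fatty acid synthase, at 0.39. Fatty acid uptake, storage and release was higher at 0.34 (0.25 to 0.43, percentile 99.8), with 6 of 10 members higher. That direction rests on genes used to name the committed class, since the median without them was -0.42, and it was -0.0082 at Leiden resolution 1. Mgll, which releases the last fatty acid from monoglycerides, stood at 124 CPM in Dpp4-type and 41.2 CPM in committed cells (-1.58). Fabp5, a fatty acid binding protein, was higher at 0.81.

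Adipogenic regulators had a median of 0.14 (0.056 to 0.26, percentile 96.6), with 8 of 13 members higher. It was 0.18 in library 1 and 0.094 (percentile 92.6) in library 2, and 0.74 over members with at least 50 CPM. It came close to 0 under other clusterings, at 0.013 with predicted doublets kept and 0.0050 with listed genes among the variable genes. Dlk1, a transmembrane protein of preadipocytes, stood at 248 and 1266 CPM (log2 fold 2.35). Cebpa was higher at 1.72 and Cebpb at 1.23, both transcription factors of adipocyte differentiation, and the Wnt antagonist Sfrp1 at 1.21. Klf4 was lower at -0.77 and Zfp521, which restrains adipogenesis, at -0.62. The list joins factors of differentiation with genes that restrain it, so the sign of its median gives no direction of adipogenesis. The extracellular matrix list had a median of 0.16 (percentile 97.9), with 12 members higher and 9 lower, and it was 0.11 (percentile 87.1) in library 2. Col4a1 and Col4a2 belong to it and also name the committed class, and the median without class markers was 0.058. With TMM scaling and every member it was 0.26. Mmp3, a matrix metalloproteinase, was higher at 2.52, and Col6a3 at 0.94. Timp3, an inhibitor of such proteases, was lower at -1.24, Fbn1 at -1.08 and Fn1, fibronectin, at -1.02. The beige and brown adipocyte programme had 3 measured members and a median of 0.45, which was 0.24 in library 1 and 0.25 in library 2, and it flipped to -0.23 at 50 CPM. Dissociation stress genes were at 0.18 (percentile 98.4), with Zfp36 at 0.79 and Nr4a1 at -1.11. Their median was 0.20 in library 1 and 0.073 (percentile 77.3) in library 2, and 0.046 at Leiden resolution 1 and 0.28 with TMM scaling. Ribosomal protein genes were at 0.11 (percentile 97.6), with 71 of 83 higher, and at 0.20 with TMM scaling.

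**Figure D2:**
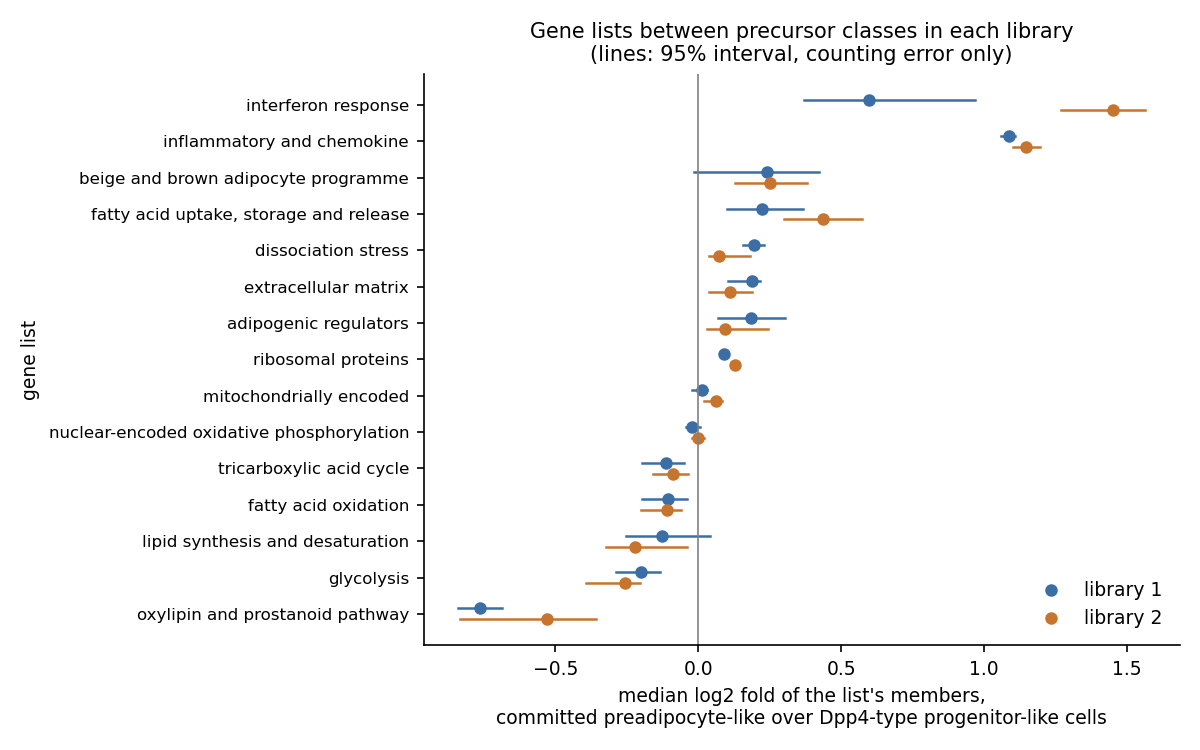
Median log2 fold of each gene list's members, committed preadipocyte-like over Dpp4-type progenitor-like cells (x axis), for the 15 lists (y axis); points are libraries and lines are 95% intervals of counting error. The inflammatory list lies at 1.09 and 1.15, the oxylipin list at -0.76 and -0.53, and fatty acid oxidation at -0.11 in each library. The median of all genes compared was -0.10 in library 1 and -0.12 in library 2 under the same scaling. The uptake list turns to -0.42 over both libraries without class markers.

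In the mm10 (GRCm38) assembly, Ptgs2 lies on chromosome 1 at 150100031 to 150108227 on the plus strand and Hpgd on chromosome 8 at 56294585 to 56321043. Cxcl12 lies on chromosome 6 at 117168535 to 117181367 and Dlk1 on chromosome 12 at 109452823 to 109463336. These are the spans of whole protein-coding genes.

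F3-type stromal-like cells were compared with Dpp4-type cells in the same way. They carried more immediate early and chemokine transcripts, and had a lower median of the oxylipin and prostanoid list. Dissociation stress genes, which respond rapidly to tissue digestion, were higher by a median of 0.65 (0.62 to 0.69, percentile 100), with 15 of 16 members higher. Hspa1b, a heat shock protein, was at 1.69, Fosb at 1.06, Dnajb1 at 1.02 and Jun at 0.96. The inflammatory list was higher at 0.80 (0.76 to 1.07, percentile 100), with 12 of 15 members higher. Cxcl12 was at 1.71, Icam1 at 1.64, Ccl11 at 1.46, Vcam1 at 1.41 and Il6 at 1.32.

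Among list genes with at least 50 CPM that name neither class, Mmp3 rose most, from 11.6 CPM in Dpp4-type to 192 CPM in F3-type cells (log2 fold 4.05). Nr2f2, a nuclear receptor, followed at 2.95, and the basement membrane collagens Col4a1 at 2.71 and Col4a2 at 2.42. Klf5, a transcription factor of early adipogenesis, was at 2.64, and Lpl, which releases fatty acids from circulating triglycerides, at 1.41. The oxylipin list was lower at -0.74 (percentile 0), with 8 of 10 members lower, and it was -1.28 in library 1 and -0.70 in library 2. Among the lower members were Hpgd at -2.80, Ptgs2 at -1.82 and Ptgis at -1.42. Fbn1 at -1.39, Timp3 at -1.38 and Mgll at -1.35 were also lower. Nuclear-encoded oxidative phosphorylation stood at -0.13 (-0.15 to -0.10, percentile 0.860) with 68 of 86 members lower, the tricarboxylic acid cycle at -0.20 (percentile 2.82) and glycolysis at -0.25 (percentile 2.62). Without the top 3% of doublet scores the first of these was -0.047 and the second -0.016. The lower level of respiration genes was thus largely lost under that setting. That setting also changed the class, since the F3-type name covered 894 cells in 2 clusters there, beside 408 cells in 1 cluster here. These values therefore do not isolate an effect of doublets. Fatty acid oxidation was at -0.13 (percentile 17.2) and lipid synthesis at -0.078 (percentile 38.5), which turned to 0.059 with members of at least 50 CPM. Mitochondrially encoded genes stood at -0.029 (percentile 44.0), the beige and brown programme at 0.23 (percentile 89.7) over 3 members and ribosomal protein genes at 0.045 (percentile 96.2), which was 0.022 in library 1 and 0.070 in library 2. Adipogenic regulators were at 0.18 (percentile 98.4) and extracellular matrix at 0.12 (percentile 98.7), which was 0.18 in library 1 and 0.046 (percentile 77.1) in library 2. The interferon list was at 0.44 (percentile 97.4) over 4 members and flipped to -0.023 with members of at least 50 CPM. Uptake, storage and release stood at 0.21 (percentile 97.9). It was 0.033 (percentile 76.6) in library 2 and 0.044 with predicted doublets kept, and it flipped to -0.21 at Leiden resolution 1 and to -0.045 with 3000 variable genes. Few cells and unstable class borders limit this contrast, since fatty acid oxidation was -0.31 at resolution 1 and -0.0067 without the highest doublet scores.

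The libraries were then set side by side within Dpp4-type cells, the largest class. Of 2140 genes with at least 50 CPM in either library, 4 were 2-fold or more higher in library 1 and 1 was 2-fold or more higher in library 2. At 1.5-fold these numbers were 7 and 4. Over all 2273 genes at that level the log2 fold had a median of -0.0068 and a standard deviation of 0.25. The 4 genes 2-fold higher in library 1 encode the alpha and beta chains of adult haemoglobin. Their log2 folds, -5.58 to -5.09, are included in that standard deviation and widen it. These values compare libraries, not diets, and there is no replicate check.

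Hbb-bs stood at 481 CPM (471 to 492) in library 1 and 10.1 CPM (8.69 to 11.6) in library 2, a log2 fold of library 2 over library 1 of -5.58. Hba-a1 was at -5.20, Hbb-bt at -5.19 and Hba-a2 at -5.09, and reads of these near-identical gene pairs can be assigned to the wrong copy. Angptl4, a secreted inhibitor of lipoprotein lipase, stood at 63.1 CPM (59.4 to 66.9) and 33.6 CPM (31.0 to 36.3), a log2 fold of -0.91. In committed cells the fold of Angptl4 was 0.061. Mfap4, a microfibril-associated glycoprotein, was at -0.75 (190 and 113 CPM) and Kcnj8, a subunit of ATP-sensitive potassium channels, at -0.72 (100.2 and 60.8 CPM). Higher in library 2 were Smpd3, a sphingomyelinase, at 1.42 (51.6 and 139 CPM) and Daglb, a diacylglycerol lipase, at 0.99 (44.8 and 88.9 CPM). Rgcc, a regulator of the cell cycle, was at 0.79 (56.4 and 97.7 CPM) and Ccl11 at 0.72 (111 and 182 CPM). Smpd3 is among the markers fixed for the Dpp4-type class, and Smpd3 and Daglb also led the unnamed cluster 2. In F3-type cells Ccl11 was at 0.0056 and Daglb at 0.36.

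**Figure D3:**
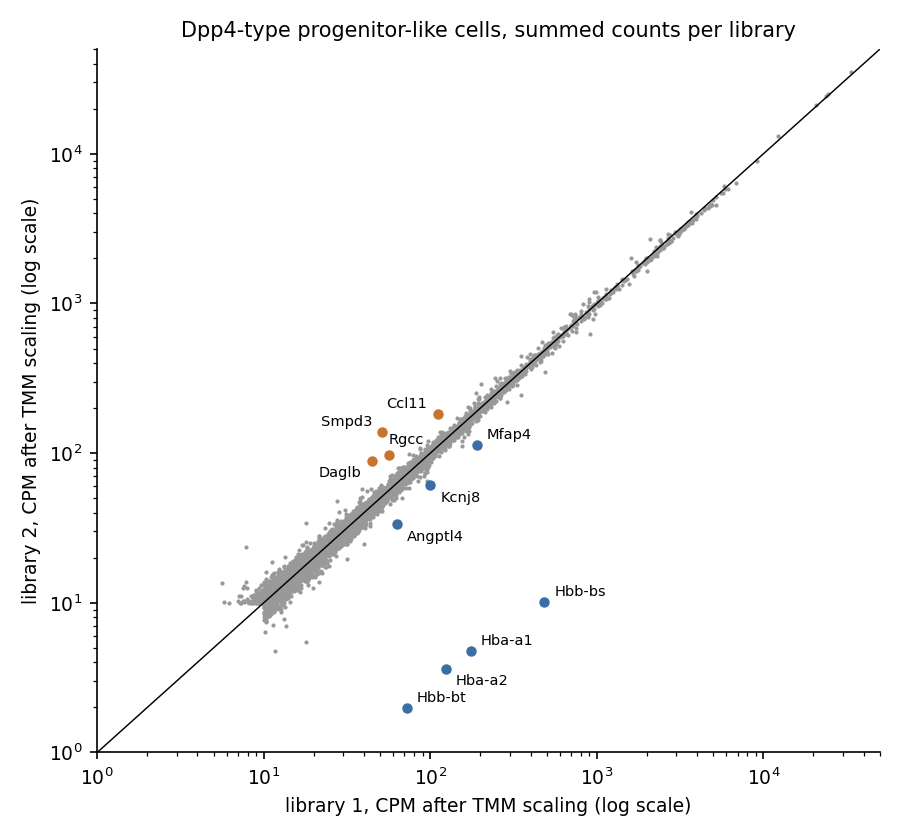
Level of each gene in library 1 (x axis) and library 2 (y axis), in CPM after TMM scaling on log axes, from summed counts of Dpp4-type cells; each grey point is a gene with at least 10 CPM in either library, the line marks equal levels, and the 11 genes named by the rule are coloured by the library in which they were higher. The 4 haemoglobin genes lie below the line, Hbb-bs at 481 and 10.1 CPM.

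In genome coordinates of mm10, Hbb-bs lies on chromosome 7 at 103826534 to 103828096 on the minus strand and Hba-a1 on chromosome 11 at 32283511 to 32284465. Smpd3 lies on chromosome 8 at 106252548 to 106337988, Daglb on chromosome 5 at 143464584 to 143505942 and Angptl4 on chromosome 17 at 33773750 to 33781830.

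Gene lists were close between the libraries in Dpp4-type cells. Fatty acid oxidation had a median log2 fold of library 2 over library 1 of -0.10 (-0.14 to -0.040), with 5 members higher and 17 lower in library 2. Its percentile among matched random lists was 0.0700, and none of its 22 members was 1.5-fold apart (0 genes). In committed cells the median was -0.059 (-0.10 to 0.028, percentile 9.33). Lipid synthesis and desaturation was higher in library 2 by 0.18 (0.045 to 0.20, percentile 100), with 8 of 12 members higher, and by 0.18 in committed cells (percentile 99.8). Within it, Elovl5 was at 0.21, Scd2 at 0.20, Scd1 at 0.19 and Fasn at 0.17. Among the oxidation genes Hadha was at -0.18, Eci2 at -0.16, Acaa2 at -0.13 and Cpt1a at -0.043, and Hadhb was at 0.24.

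Fatty acid uptake, storage and release stood at -0.065 (percentile 6.67), with Cd36, a fatty acid translocase, at -0.44 and Fabp4 at -0.31. The oxylipin list was at -0.090 (-0.12 to 0.034, percentile 1.57) in Dpp4-type cells and at 0.16 (-0.058 to 0.26, percentile 98.6) in committed cells. Both intervals held 0, so its sign was settled in neither class. Hpgd was at -0.54 in Dpp4-type and -0.78 in committed cells. The inflammatory list was at 0.13 (0.052 to 0.15, percentile 99.99), and it was -0.083 in F3-type cells. Within Dpp4-type cells it was 0.026 in Xist-positive and 0.23 in Y-positive cells, and 0.023 with members of at least 50 CPM. C3, complement component 3, was at 1.61 (7.80 and 23.8 CPM) and at 1.02 in committed cells. The interferon list was at 0.0051 (percentile 54.5) over 3 members in Dpp4-type cells and at 0.36 (percentile 99.96) over 6 in committed cells. Adipogenic regulators were at 0.089 (percentile 99.3) and turned to -0.025 in committed cells and -0.029 over all kept cells, with Klf4 at 0.32 and 0.31. Extracellular matrix was at 0.041 (percentile 99.6) and turned to -0.0080 in committed cells and -0.0025 in Xist-positive cells, and Eln, elastin, was at -0.56 and -0.55.

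Dissociation stress genes stood at -0.059 (percentile 1.70) in Dpp4-type and -0.14 (percentile 0) in committed cells, and turned to 0.13 in F3-type cells. Ribosomal protein genes were at -0.061 (percentile 0) and turned to 0.0036 in committed and 0.035 in F3-type cells. Glycolysis was at 0.092 (percentile 99.7) and at 0.0080 with members of at least 50 CPM. The tricarboxylic acid cycle was at 0.014 (percentile 75.1), nuclear-encoded oxidative phosphorylation at -0.0081 (percentile 39.9) and mitochondrially encoded genes at 0.023 (percentile 92.2), which turned to -0.025 in Xist-positive cells. The beige and brown programme had 2 measured members and stood at -0.12 (percentile 10.3), turning to 0.097 in committed cells. Percentiles describe these libraries, and list medians of this size have no replicate error to be held against.

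Haemoglobin transcripts were spread over the cells of library 1. Over clusters 0 to 8, the median Hbb-bs level over cells lay between 419 and 513 CPM, and it was 509 CPM in macrophage or monocyte-like cells, which should lack the gene. In library 1 an Hbb-bs UMI was seen in 1334 of 1352 Dpp4-type cells (median depth 13727.5 UMIs) and in 26 of 26 macrophage or monocyte-like cells (median depth 7937.5 UMIs), so its level in precursors is at background. Summed CPM was higher in cycling-like (2640) and endothelial-like cells (17857). In library 2 the median was 0 in each of these clusters, but endothelial-like cells held 1790 Hbb-bs UMIs (3907 CPM), found in 10 of 26 cells.

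**Figure D4:**
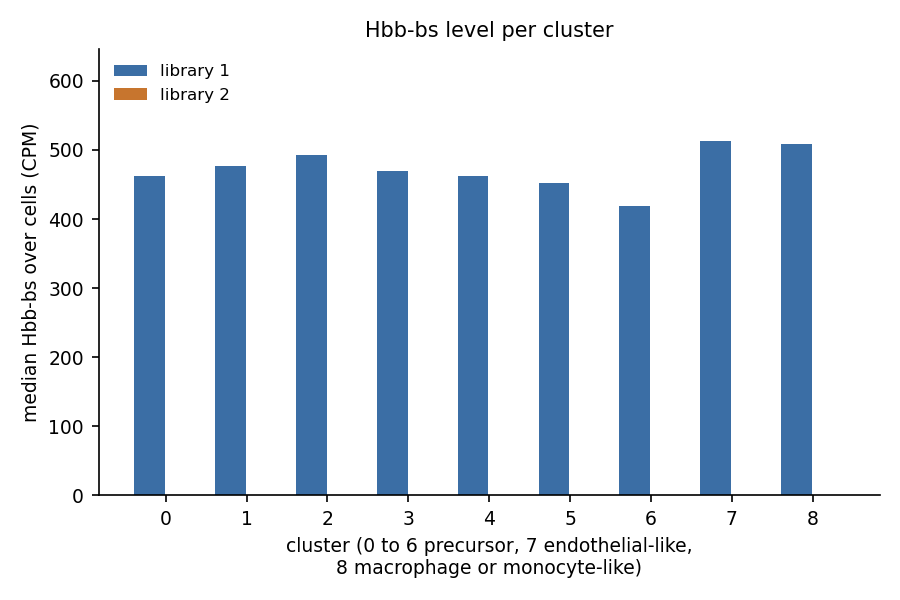
Median Hbb-bs level over cells (CPM, y axis) in clusters 0 to 8 (x axis), with library 1 and library 2 as separate bars. Medians of library 1 lie between 419 and 513 CPM and those of library 2 at 0, although 10 of 26 endothelial-like cells of library 2 held an Hbb-bs UMI.

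Cells with 2 or more UMIs of Mki67 or Top2a, genes of dividing cells, made up 2.63% of library 1 (2.12 to 3.24, 87 of 3302 cells) and 3.58% of library 2 (3.00 to 4.24, 128 of 3575 cells). By class, 0 of 191 F3-type cells of library 1 (upper bound 1.91%) and 0.461% of 217 in library 2 passed the same count, at median depths of 11474 and 10204 UMIs. For Dpp4-type cells these shares were 0.370% and 0.613%, for committed cells 1.18% and 0.547%, for macrophage or monocyte-like cells 3 of 26 and 1 of 20, and for endothelial-like cells, which can hold doublets, 4 of 23 and 5 of 26. No class is a neutral background, because many cycling cells had been drawn into their own cluster. With every cell thinned to 7464 UMIs the shares were 1.88% (1.42 to 2.44) and 2.79% (2.25 to 3.41). In Xist-positive cells they were 2.44% and 2.61%, and in cells with Y-linked transcripts 2.81% and 3.86%. With a minimum of 1 UMI the shares were 9.78% (8.79 to 10.8) and 12.2% (11.1 to 13.3). The intervals of the libraries overlapped at 2 UMIs and did not at 1 UMI, and free RNA of these genes was not excluded as a source of such calls.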

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

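All tests in this part, and the bounds they were read against, were chosen only after the result was seen.

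Erythroid-like cells made up 0.545% of library 1, and stand here as a signal outside the sorted precursors for which there is no control sample. In the other clusters of library 1 the median Hbb-bs level over cells differed by a factor of at most 1.22, and macrophage or monocyte-like cells had 1.02 times (0.850 to 1.21) the level of Dpp4-type cells, which argues against transcription by the precursors themselves. The ratio of Hbb-bs to Hba-a1 UMIs was 2.76 in Dpp4-type and 1.57 in erythroid-like cells, 1.76 times apart (1.68 to 1.83), which argues against release only by cells like those captured, although these genes have near-identical copies that can share reads. Summed levels were higher in cycling-like (2640 CPM) and endothelial-like cells (17857 CPM), with ratios of 1.38 and 2.01, while their medians over cells, 452 and 513 CPM, were like those of other clusters. A shared background therefore fits the typical cell there but not the excess in the sums. Free RNA in every droplet may account for the level in most cells, its origin stays open, and no biological explanation was tested.

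Cells with at least 6 Xist UMIs and at least 2 Y-linked UMIs made up 1.06% of library 1 and 0.811% of library 2, a signal outside the comparisons, at median depths of 18400 and 17299 UMIs. Saa3, an acute phase gene, was lower in committed than in Dpp4-type cells of library 1 (log2 fold -1.02, -1.75 to -0.34) and higher in library 2 (3.95, 3.40 to 4.54), a difference that was not tested. In library 2, 1 committed cell held 178 of the 247 Saa3 UMIs of its class. In library 1, 1 Dpp4-type cell held 28 of 83, and the gene was seen in 23 of 1352 Dpp4-type and 14 of 851 committed cells. Both folds therefore lean on single cells, which the counting intervals do not cover.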

How the results depend on the processing

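Settings chosen only after the data were seen were the removal of the top 3% of doublet scores, other clusterings and TMM for list medians between classes, medians without class markers, and libraries compared within committed, F3-type, Xist-positive or Y-positive cells, while the other settings were planned. Of 270 list medians between classes under other settings, 182 stayed within their counting interval, 80 moved outside it and 8 turned sign. For 135 list medians between libraries these numbers were 91, 34 and 10. Of 40 counts of genes, 31 stayed within 1.5 times and 9 did not, and of 76 shares of cells 25 stayed within their interval and 51 moved. Folds of named genes between classes stayed within their interval in 57 of 170 cases and moved in 113, with 0 sign turns, and between libraries 89 of 135 stayed, 44 moved and 2 turned sign. A sign turn is counted only where the interval of the value reported left out 0. Counting intervals are narrow at this depth, so many values moved by little. Class borders were unstable: of 1765 committed cells, 1262 kept that name with 8 more barcodes and 1277 at Leiden resolution 1, where 1067 of 2820 Dpp4-type cells kept theirs. No paired analysis was possible because each condition has 1 library and no test was made. Apart from the minimum level, which changes the members of a list, the cause was not tested.

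Barcodes passing the filters made up 98.5% with 200 genes and 5% mitochondrial counts, 99.4% with 1000 genes and 96.7% without the top 3% of doublet scores. Dpp4-type cells made up 16.1% at Leiden resolution 1, 47.5% with 3000 variable genes, 37.8% with listed genes among the variable genes and 42.5% without the top doublet scores. The committed share was 18.6% at Leiden resolution 1, 18.6% with predicted doublets kept and 19.6% with listed genes. The F3-type share was 10.4% at Leiden resolution 1, 9.28% with doublets kept and 13.4% without the top doublet scores. The cycling-like share was 3.999% at Leiden resolution 1, 5.32% with 3000 variable genes, 3.72% with doublets kept, 4.70% with listed genes and 4.46% without the top doublet scores. Cells with Mki67 or Top2a made up 9.78% and 12.2% of libraries 1 and 2 at a minimum of 1 UMI, 1.88% and 2.79% after thinning, and 2.61% of Xist-positive cells in library 2. With no minimum level, 877 genes were 2-fold and 1450 were 1.5-fold higher in library 1, and 788 and 1344 in library 2, counts that include genes with few UMIs. In F3-type cells 12 genes were 1.5-fold higher in library 1. Genes 2-fold higher in library 2 numbered 3 over all kept cells, 2 after thinning, 0 in F3-type cells and 3 in Y-positive cells. Angptl4 turned sign in committed cells (0.061) and Scd1 in F3-type cells (-0.31).

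The values that follow are median log2 folds of lists, first of committed over Dpp4-type cells. With Leiden resolution 1 it was -0.29 for fatty acid oxidation, -0.30 for lipid synthesis, -0.0082 for uptake (sign turned), -0.75 for oxylipins and -0.25 for the tricarboxylic acid cycle. Also with Leiden resolution 1 it was -0.083 for oxidative phosphorylation, -0.47 for glycolysis, 1.56 for inflammatory genes, 1.22 for interferon response and 0.046 for dissociation stress. Also with Leiden resolution 1 it was 0.17 for ribosomal proteins. With TMM scaling it was -0.043 for fatty acid oxidation, 0.012 for the tricarboxylic acid cycle (sign turned), 0.079 for oxidative phosphorylation, 0.14 for mitochondrially encoded genes and -0.16 for glycolysis. Also with TMM scaling it was 0.26 for extracellular matrix, 1.15 for inflammatory genes, 1.17 for interferon response, 0.28 for dissociation stress and 0.20 for ribosomal proteins. With members of at least 50 CPM it was 0.057 for lipid synthesis (sign turned), 0.81 for uptake, -1.34 for oxylipins, -0.19 for glycolysis and -0.23 for the beige programme (sign turned). Also with members of at least 50 CPM it was 0.74 for adipogenic regulators, 1.13 for inflammatory genes and 0.34 for interferon response. With predicted doublets kept it was 0.45 for uptake, 0.070 for mitochondrially encoded genes, 0.013 for adipogenic regulators, 1.23 for inflammatory genes and 1.32 for interferon response. Also with predicted doublets kept it was 0.15 for ribosomal proteins. With listed genes among the variable genes it was 0.66 for uptake, -0.035 for the tricarboxylic acid cycle, 0.015 for oxidative phosphorylation, 0.077 for mitochondrially encoded genes and 0.0050 for adipogenic regulators. Also with listed genes among the variable genes it was 0.90 for interferon response and 0.24 for dissociation stress. With class markers left out it was -0.42 for uptake (sign turned), 0.058 for extracellular matrix and 0.99 for inflammatory genes. With 3000 variable genes it was -0.042 for the tricarboxylic acid cycle, 0.0093 for oxidative phosphorylation, 0.067 for mitochondrially encoded genes, 0.99 for inflammatory genes and 0.72 for interferon response. Also with 3000 variable genes it was 0.21 for dissociation stress and 0.11 for ribosomal proteins. With the mean over cells it was 0.12 for ribosomal proteins.

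For F3-type over Dpp4-type cells the same medians differed from the values reported as follows. With Leiden resolution 1 it was -0.31 for fatty acid oxidation, -0.21 for uptake (sign turned), -0.20 for oxidative phosphorylation, -0.37 for glycolysis and 0.55 for the beige programme. Also with Leiden resolution 1 it was 0.25 for extracellular matrix, 0.55 for dissociation stress and 0.079 for ribosomal proteins. With the top 3% of doublet scores left out it was -0.0067 for fatty acid oxidation, -0.016 for the tricarboxylic acid cycle, -0.047 for oxidative phosphorylation, 0.16 for extracellular matrix and 0.74 for inflammatory genes. Also with the top 3% of doublet scores left out it was 0.69 for dissociation stress and 0.025 for ribosomal proteins. With members of at least 50 CPM it was -0.22 for fatty acid oxidation, 0.059 for lipid synthesis, -1.62 for oxylipins, -0.17 for glycolysis and 1.42 for the beige programme. Also with members of at least 50 CPM it was 0.61 for inflammatory genes and -0.023 for interferon response (sign turned). With predicted doublets kept it was 0.044 for uptake, 0.58 for inflammatory genes, 0.52 for dissociation stress and 0.038 for ribosomal proteins. With 3000 variable genes it was -0.045 for uptake (sign turned), -0.16 for oxidative phosphorylation and 0.60 for dissociation stress. With listed genes among the variable genes it was 0.36 for uptake, 0.026 for mitochondrially encoded genes, -0.17 for glycolysis, 0.69 for inflammatory genes and 0.59 for dissociation stress. Also with listed genes among the variable genes it was 0.023 for ribosomal proteins.

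For library 2 over library 1, medians are within Dpp4-type cells unless others are named. Within F3-type stromal-like cells it was -0.14 for fatty acid oxidation, -0.20 for uptake, 0.082 for the tricarboxylic acid cycle, 0.070 for mitochondrially encoded genes and -0.083 for inflammatory genes (sign turned). Also within F3-type stromal-like cells it was -0.13 for interferon response, 0.13 for dissociation stress (sign turned) and 0.035 for ribosomal proteins (sign turned). Within Y-positive cells it was -0.14 for fatty acid oxidation, 0.020 for oxidative phosphorylation, 0.058 for mitochondrially encoded genes, 0.10 for extracellular matrix and 0.23 for inflammatory genes. Also within Y-positive cells it was 0.30 for interferon response, -0.037 for dissociation stress and -0.051 for ribosomal proteins. Within committed preadipocyte-like cells it was 0.16 for oxylipins, 0.027 for oxidative phosphorylation, 0.069 for mitochondrially encoded genes, 0.097 for the beige programme (sign turned) and -0.025 for adipogenic regulators (sign turned). Also within committed preadipocyte-like cells it was -0.0080 for extracellular matrix (sign turned), 0.36 for interferon response, -0.14 for dissociation stress and 0.0036 for ribosomal proteins (sign turned). With total scaling it was 0.0022 for oxidative phosphorylation and -0.050 for ribosomal proteins. With DESeq2 size factors it was 0.0017 for oxidative phosphorylation and -0.051 for ribosomal proteins. Within all kept cells it was 0.0062 for oxidative phosphorylation, 0.037 for mitochondrially encoded genes, -0.029 for adipogenic regulators (sign turned), 0.020 for extracellular matrix and 0.20 for interferon response. Also within all kept cells it was -0.12 for dissociation stress and -0.039 for ribosomal proteins. Within Xist-positive cells it was -0.025 for mitochondrially encoded genes (sign turned), -0.0025 for extracellular matrix (sign turned), 0.026 for inflammatory genes and -0.076 for ribosomal proteins. With members of at least 50 CPM it was 0.0080 for glycolysis and 0.023 for inflammatory genes. With the top 3% of doublet scores left out it was 0.16 for inflammatory genes and -0.050 for ribosomal proteins.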

Other observations

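The tests on the 7 genes in the last paragraph were chosen only after the result was seen, and the levels given before it involve no test of an explanation.

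Summed levels of the gene lists also differed outside the classes compared so far. Unnamed cluster 3, led by the matrix genes Cilp, Eln and Mfap4, had 15528 CPM of dissociation stress genes beside 7499.7 CPM in Dpp4-type cells, and 7432 CPM of inflammatory and chemokine genes beside 8594 CPM. Jun and Hspa1a, members of the stress list, were among its 10 leading genes. Macrophage or monocyte-like cells had 16951 CPM of the inflammatory list, close to the 16670 CPM of committed cells. The macrophage or monocyte-like cluster also held 56343 CPM of extracellular matrix genes, beside 93276 CPM in committed cells. Free RNA or doublets can therefore be part of its inflammatory level. Genes of fatty acid oxidation summed to between 860.1 CPM in F3-type cells and 1181 CPM in unnamed cluster 6 among precursor clusters. They reached 1614 CPM in endothelial-like cells, which also had 28197 CPM of uptake, storage and release genes and which can hold doublets.

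Ifit1, an interferon-induced gene, had a log2 fold of library 2 over library 1 of 1.48 (1.15 to 1.82) in committed cells, at 10.1 and 28.0 CPM of the total count. In Dpp4-type cells it stood at 6.71 and 8.13 CPM, below the 10 CPM minimum for list members, and its fold was 0.27 with an interval that held 0 (-0.088 to 0.62). Within Dpp4-type cells it was -0.56 (-1.17 to 0.040) in Xist-positive and 1.63 (0.82 to 2.53) in Y-positive cells. Xist-positive cells without Y-linked UMIs made up 42.2% of library 1 (40.5 to 43.9) and 40.8% of library 2 (39.1 to 42.4), and Y-positive cells 24.8% (23.3 to 26.3) and 29.7% (28.2 to 31.3). No cell type lacks both kinds of transcript, so these shares have no background value.

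Angptl4, Mfap4, Kcnj8, Smpd3, Daglb, Rgcc and Ccl11 were 1.5-fold or more apart between the libraries in Dpp4-type cells, with a median absolute log2 fold of 0.79. It was 0.82 within Xist-positive and 0.83 within Y-positive cells, which argues against a different mix of these cells as the whole cause. Within each library, the shallower Dpp4-type cells were set against the deeper ones, which differed in median depth by a factor of 1.31 in library 1 and 1.32 in library 2, beside 1.06 between the libraries. Signed by the direction between the libraries, the median log2 fold of the 7 genes, shallower over deeper, was 0.033 in library 1 and 0.16 in library 2, which argues against depth per cell as the whole cause. The gap in UMIs per cell differed between Dpp4-type and committed cells by over a factor of 2 for 6 of the 7 genes, all but Ccl11 (0.840), which argues against free RNA as the whole difference. A library batch or the diet may account for these folds, and with 1 library per diet and no diet known for either library they cannot be told apart.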
